A study of Mus musculus with 2 samples.

How the data were processed

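Total RNA of mouse liver was profiled for long non-coding RNAs (lncRNAs) in 2 libraries, 1 from a mouse sample on a high fat diet and 1 from a sample on a normal diet. Each library was assigned to its diet from the diet label. The labels name hepatocytes as the source, while the extraction protocol describes whole liver that was removed, frozen and extracted with Trizol, so the values are taken as those of liver tissue. The labels say nothing on pooling of animals.

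Per the submitters' processing notes, HISAT2, HTSeq and DESeq were used and the genome build was mm8. Versions, the role of each tool, the annotation and the strand setting are not given in the sources used here. The deposited data are 2 tables that list both libraries side by side, 1 for 614 known lncRNAs with Ensembl gene identifiers and 1 for 272 lncRNAs that carry numbers in place of names. Values in both deposited tables are CPM, reads of an lncRNA scaled so that each library's reads of that table sum to 1000000, and the file headers call them normalized. The deposited fold change is the ratio of the high fat diet value to the normal diet value, and the deposited log2 column is its log2. The authors' tables also give p-values and adjusted p-values, which are printed only as theirs. Recomputed on read pairs, the deposited p-values equalled a normal approximation of the log ratio at a given mean level under random sampling of reads, to a relative deviation of at most 7.39e-13 over 613 known and 3.70e-13 over 272 numbered lncRNAs. That formula holds counting error and no spread between animals. The authors' adjusted p-values were 0.756 (known) and 0.744 (numbered) times the Benjamini-Hochberg value and lay below the unadjusted p for 172 and 79 lncRNAs.

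Whole reads were recovered by dividing each CPM value by the smallest value of its column, which was taken as 1 read. In this way 100% of the values came out whole to within 1e-06. The listed lncRNAs held 193260 reads (high fat diet) and 241812 reads (normal diet) in the known table and 25074 and 36376 reads in the numbered table, with values of 1 read taken as 0. The totals to which the CPM values were scaled, 1000000 divided by the value of 1 read, were slightly larger, at 193538 and 242194 reads and at 25270 and 36634 reads. The difference of 278, 382, 196 and 258 reads belongs to no listed lncRNA. Ratios, intervals and shares use the scaling totals, and the depth of the whole libraries is not known from them. All recovered numbers other than 1 were even, and the deposited p-values were reproduced on pairs, so intervals were computed on read pairs of 2 reads each. The read numbers printed here are therefore 2 per pair counted, and a minimum of 20 reads is a minimum of 10 pairs. A value of exactly 1 read, found for 7 and 1 known and 19 and 7 numbered lncRNAs in the high fat diet and normal diet library, was treated as 0 pairs. A fold against such a value was taken against a floor of 3 pairs, or 6 reads, per library. This fold leaves out counting error, so the lower limit of the exact interval is given beside it. The floor corresponds to 31.0 and 24.8 CPM in the known table and 237 and 164 CPM in the numbered table.

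With 1 library per diet there is no replicate check and no test of the diets. An lncRNA was called higher or lower when the CPM values differed at least 2-fold with at least 20 reads in the higher library. Each log2 ratio has an exact (Clopper-Pearson) 95% interval from the binomial split of the read pairs, which covers counting error only. The rule had been set for either counts or normalized values before the data were examined. Its minimum of 1 for normalized values lies below the value of 1 read (5.17 and 4.13 CPM, 39.6 and 27.3 CPM), so the 20-read minimum was applied to the recovered reads. The change from reads to read pairs in the intervals was also made after the data were examined. The split of higher against lower lncRNAs was compared between the tables with a two-sided Fisher's exact test, which describes these libraries because lncRNAs are not replicates. The tables were normalized separately, so their levels were not compared. Numbers of calls and their directions were compared between them, and the closing section compares the recovered read numbers and log2 ratios of lncRNAs listed with the same reads in both.

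The named lncRNAs are the 10 with the largest and the 10 with the smallest log2 ratio among those called in the known table, the 5 and 5 by the same rule in the numbered table, the 5 most abundant of each table, and each measured member of 13 gene lists written before the data were examined. Known lncRNAs called with at least 1000 reads in the higher library were added after the values were seen. Lists covered nuclear and abundant, snoRNA host, imprinted, X-inactivation, hepatic metabolic, microRNA host and non-hepatocyte cell lncRNAs, and 6 sets of coding genes (lipid synthesis and storage, fatty acid oxidation, sterol and bile acid, acute phase and inflammation, matrix and stellate cell, sex-biased and detoxification). A comparison with random lists needed 5 measured members, which no list had.

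Names, exons and neighbouring genes came from GENCODE M21, which matched 606 of the 614 identifiers. It annotates 5 of the matched genes as protein-coding. Because the submitters' notes name another build, only chromosome names and overlaps between genes are given, without coordinates. Exon overlaps were computed with bedtools 2.31.1. A coding exon here is any annotated exon of a protein-coding gene, whether translated or not. At least 50 bases counted as an overlap with a coding exon in group comparisons, while the alternative that leaves out overlapping lncRNAs drops overlaps of any size. Near-identical stretches, of at least 100 bases at 95% identity, were searched among the annotated transcripts with BLAST+ 2.17.0. A gene elsewhere with such a stretch counts as a copy, whatever share of the transcript it covers. These settings, and the minimum of 60 reads for matching read numbers between tables, were chosen after the data were examined. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

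The rule and the intervals were tested on simulated data with 4-fold changes, which lie beyond the 2-fold threshold. The simulated read pairs varied by counting error alone. The rates below hold no spread between animals and give no error rate for differences between the diets. In 614 simulated known lncRNAs, 127 of the 200 changed ones had expected reads at or above the read minimum. Of those, 95.3% were called, 0 in the wrong direction, while 2.56% of the unchanged ones with expected reads at or above it were called. Among 272 simulated numbered lncRNAs the values were 64 of 136, 95.3%, 0 and 3.64%. The intervals held the true ratio in 97.5% and 97.0% of cases. Alternatives to the scaling, read minimum, fold threshold, pseudocount and the authors' adjusted p were set beforehand. An exact binomial test of the read pairs, other scaling totals and 3 ways of leaving lncRNAs out were added after the data were examined.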

Results

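LncRNA levels were measured by RNA sequencing in the livers of C57BL/6 wild-type mice at postnatal week 27, to compare a diet with 60% fat given for 23 weeks with a normal diet. There was 1 library per diet, so values are given per library without replicate error and their intervals cover counting error only. The listed known lncRNAs held 193260 reads in the high fat diet library and 241812 reads in the normal diet library. The listed numbered lncRNAs, which have no names or positions here, held 25074 and 36376 reads. A known lncRNA had a median of 24 and 30 reads and a numbered one 8 and 14.

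Among known lncRNAs, Gm26584 (ENSMUSG00000097474, chromosome 8) was 5.40-fold lower in the high fat diet library (95% interval 5.02 to 5.81), with 1660 reads against 11208. Its exons overlap those of Slc7a2, a cationic amino acid transporter gene, on the opposite strand by 635 bases. Gm28592 (ENSMUSG00000100113, chromosome 10), opposite Phlda1 with 727 shared bases, was 4.83-fold higher (4.30 to 5.45), with 2712 reads against 702. Both Gm15713 and Gm9968 lie on chromosome 16 and overlap the span of Zbtb20, which encodes a zinc finger repressor of alpha-fetoprotein in liver. They were 3.27-fold (2.82 to 3.80) and 3.17-fold (2.79 to 3.61) higher.

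The other known lncRNAs called with at least 1000 reads were Gm44662 and 4732463B04Rik. Gm44662 (chromosome 7), opposite exons of the hepcidin gene Hamp2 and of the transcription factor gene Usf2, was 2.68-fold higher (2.33 to 3.09). In contrast, 4732463B04Rik (chromosome 12), opposite the acyl-CoA thioesterase genes Acot4 and Acot3, was 2.42-fold lower (2.16 to 2.72), with 772 reads against 2340. The strand setting of the counting is not given in the sources used here. Reads of those that overlap coding exons, all of the 6 but Gm15713, therefore cannot be told apart from reads of the coding genes. Gm15713 overlaps the span of Zbtb20 but none of its coding exons, and reads of Zbtb20 outside those exons are not excluded for Gm15713. Overlap with coding exons was not more frequent among called lncRNAs in general. Of lncRNAs that shared at least 50 bases with coding exons and reached the read minimum, 20 of 175 (11.4%) were called, against 38 of 189 (20.1%) of the others. The 175 had a median of 426 reads over both libraries and the 189 a median of 118, and 14 of the 20 with the most reads overlap coding exons in this way. The 6 lncRNAs with at least 1000 reads were singled out after their values were seen, although Gm26584, Gm28592 and Gm15713 also fall under the rule set beforehand.

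Among the called lncRNAs, the largest ratios toward the high fat diet library were those of Gm28182 (chromosome 9), with 86 reads against 4 and a log2 ratio of 4.75 (95% interval 2.81 to 7.84), F730035M05Rik, with 36 against 4 (3.49, 1.43 to 6.65), and Gm29483, with 56 against 8 (3.13, 1.62 to 5.10). F730035M05Rik lies on chromosome 12 and overlaps the span of Pygl, the gene of liver glycogen phosphorylase, but none of its coding exons. Reads of Pygl outside its exons are not excluded for F730035M05Rik. 4933440J02Rik was 4.92-fold higher (2.70 to 9.57), with 110 reads against 28. Lsmem2, Gm26782, A330033J07Rik and Gm28872 had log2 ratios from 1.69 to 2.06 with 20 to 36 reads in the high fat diet library. Their intervals excluded 0 but are not adjusted for the number of lncRNAs. The exact binomial test of the read pairs ends each of these calls. Of these, Gm26782 lies opposite Tep1 and shares near-identical stretches with 23 genes elsewhere. A330033J07Rik lies opposite Id4 by 82 bases and shares 672 exon bases with the lincRNA Gm49291 on the same strand. Gm28872 lies opposite Rnu11, the U11 small nuclear RNA, over 134 of its 158 exon bases. Reads in these overlaps cannot be told apart from reads of the overlapping genes.

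Among the called lncRNAs, those with the smallest ratios were Gm28265, with 2 reads in the high fat diet library against 32 (log2 ratio -3.68, 95% interval -9.07 to -0.99), 3930402G23Rik, with 4 against 44 (-3.14, -6.27 to -1.11), and Gm31693, with 2 against 20 (-2.998, -8.44 to -0.18). Gm26906 (chromosome 12), with 4 reads against 36 (-2.85, -6.00 to -0.78), overlaps 1228 bases of exons of Meg3, an imprinted lncRNA, on the opposite strand. This is the whole exon length of Gm26906, so without the strand setting its reads cannot be told apart from reads of Meg3. D730045A05Rik, A630072L19Rik, 4933413J09Rik and Mkln1os had log2 ratios from -2.68 to -2.07, with intervals that excluded 0. The exact binomial test of the read pairs ends the calls of Gm31693, A630072L19Rik and 4933413J09Rik. Gm44427, with 4 reads against 20 and near-identical stretches in 10 genes elsewhere, was lower by the rule. Its interval of -5.23 to 0.23 included 0, and the exact binomial test ends its call too. A630072L19Rik overlaps Ccdc88c exons and Mkln1os overlaps Mkln1 exons on the opposite strand.

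**Figure D1:**
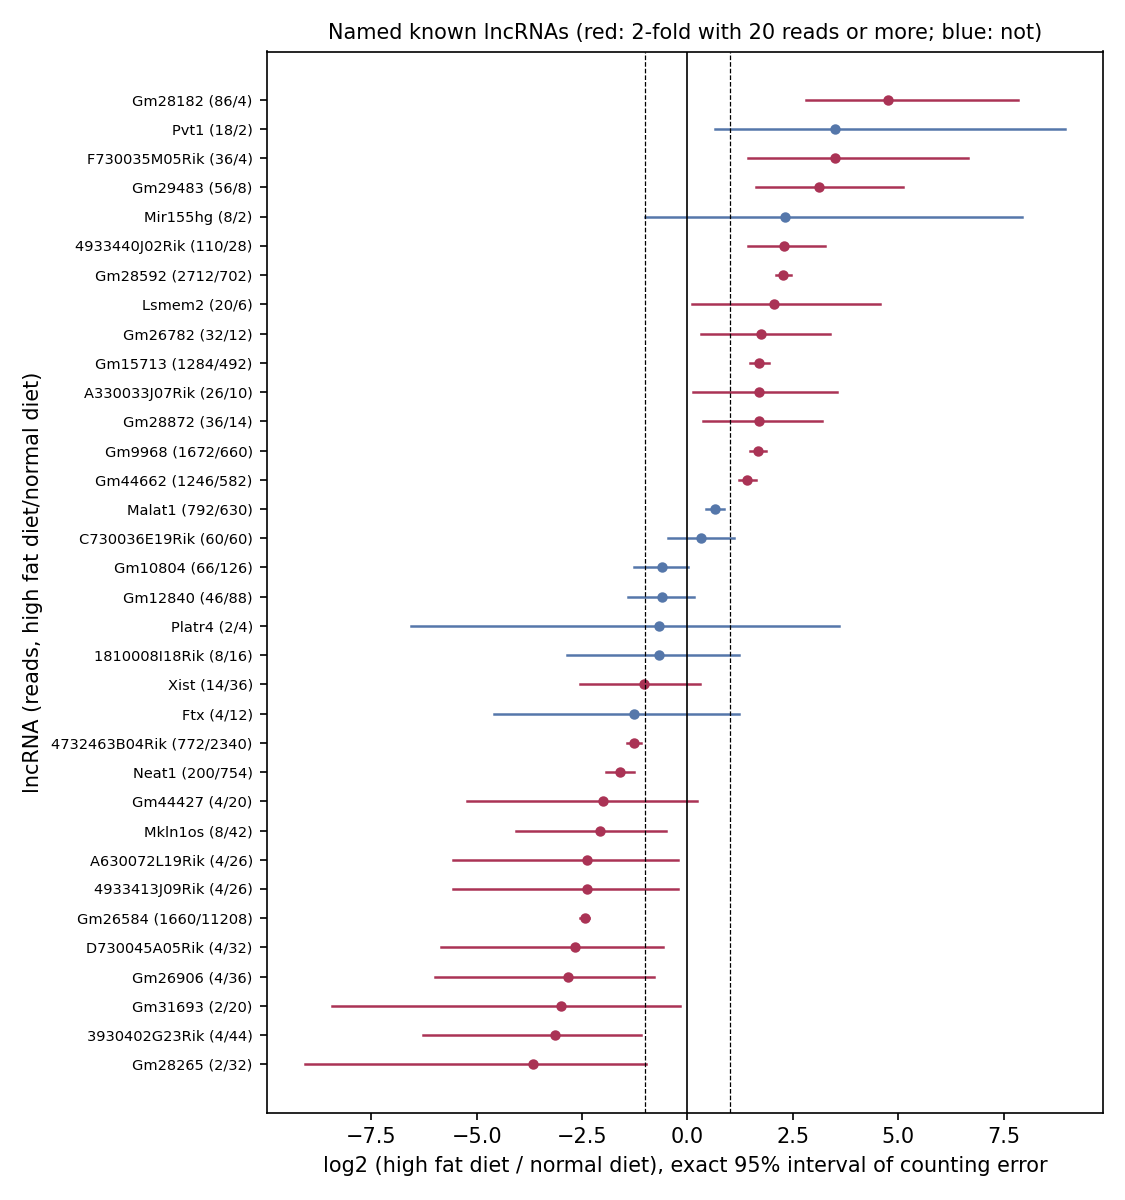
Log2 ratios of high fat diet to normal diet for the named known lncRNAs except the 5 most abundant, 1 line each, with the reads of both libraries beside the name. Points are ratios from 1 library per diet, bars are exact 95% intervals of counting error, dashed lines mark 2-fold, red marks lncRNAs called by the rule and blue the others. Gm26584 and Gm28592 have narrow intervals beyond 2-fold, while the intervals of Gm28265 and Gm28182 span several log2 units.

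Over the whole known table, 28 lncRNAs were higher and 30 lower in the high fat diet library, out of 364 that had at least 20 reads in the higher library. The interval excluded 0 for 25 of the higher and 23 of the lower ones, and lay beyond 2-fold for 8 and 6. Of 306 lncRNAs with at least 20 reads in both libraries, 225 (73.5%) differed by less than 1.5-fold. The authors' deposited table marks 20 as higher and 22 as lower, and 37 of these 42 are among the 58 called here. The remaining 5, named after their values were seen, are Pvt1, 5330411O13Rik, Gm16025, Gm12088 and Gm26634, each with fewer than 20 reads in both libraries. An exact binomial test of the read pairs, which compares these libraries and not the diets, leaves 15 higher and 16 lower at a Benjamini-Hochberg value under 0.05.

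The 5 most abundant known lncRNAs differed by less than 2-fold between the libraries. Gm30097, opposite Fgg, the fibrinogen gamma chain gene, held 10.96% (95% Clopper-Pearson interval 10.8 to 11.2) of the known-table read pairs in the high fat diet library and 9.77% (9.60 to 9.94) in the normal diet library. 1810014B01Rik, opposite the endoplasmic reticulum chaperone gene Hsp90b1, was 1.58-fold higher (1.53 to 1.63). Gm26809, Gm26905 and Gm26697 had log2 ratios of -0.21, -0.18 and -0.28. Gm26697 lies opposite Slc27a2, a very long chain acyl-CoA synthetase gene, and Gm26905 shares near-identical stretches with 98 genes elsewhere. Together these 5 held 41.9% (41.6 to 42.3) and 40.6% (40.3 to 40.9) of the pairs.

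**Figure D2:**
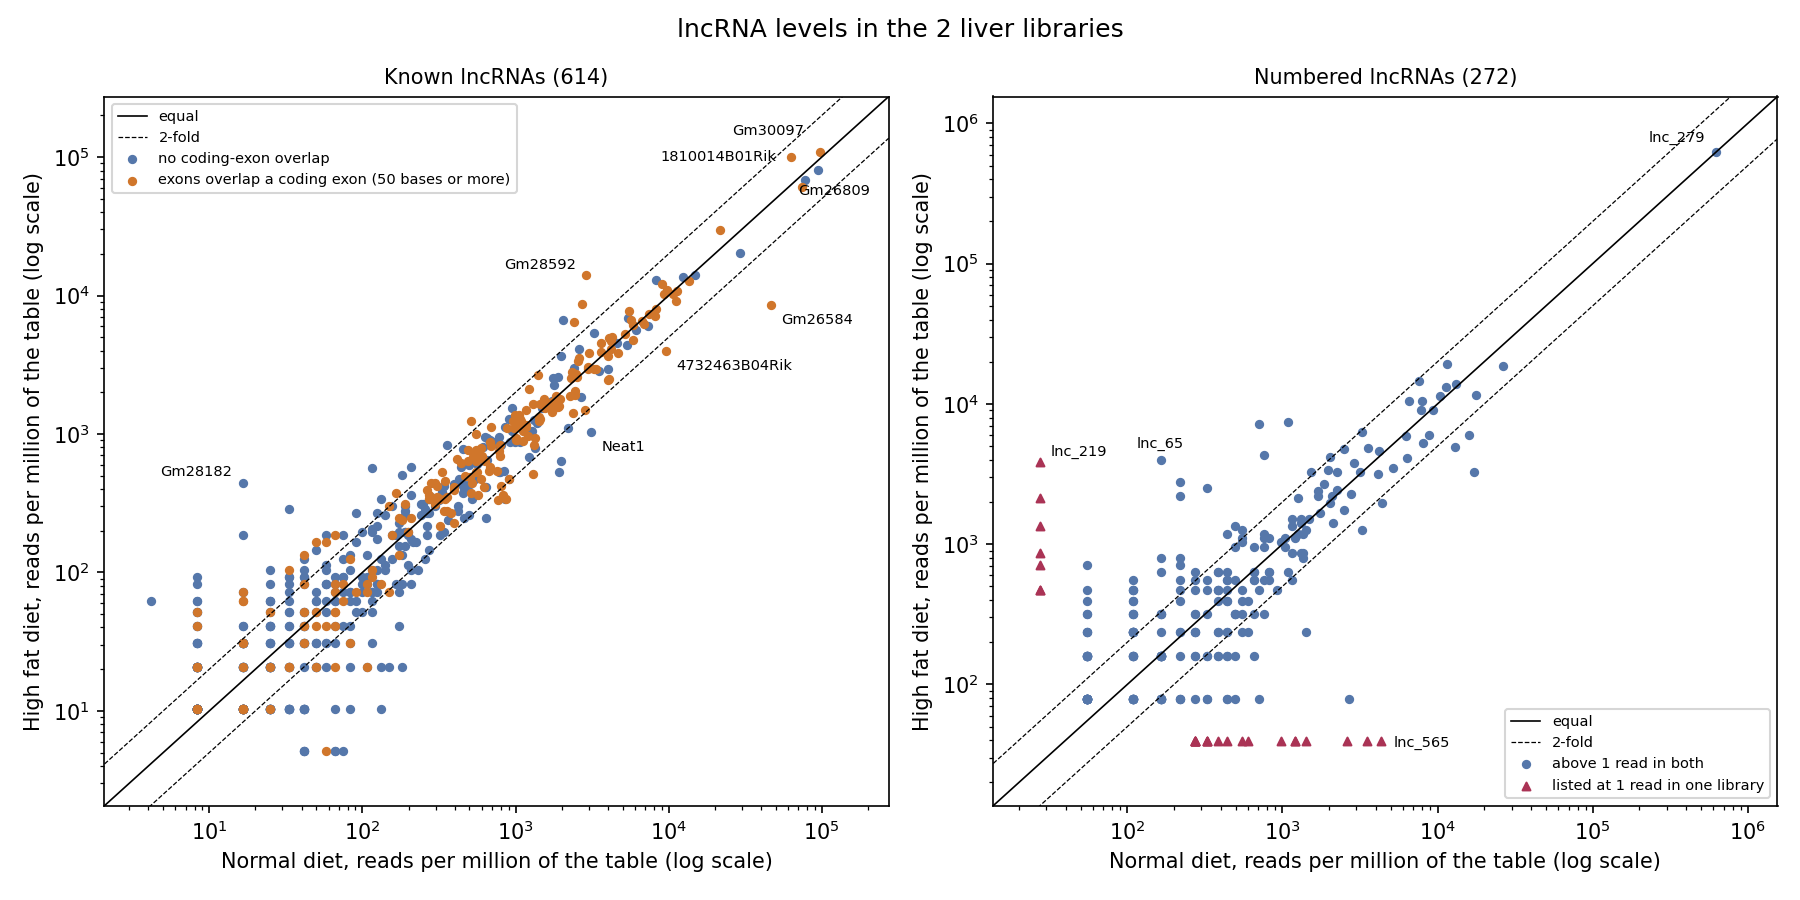
CPM of each lncRNA in the high fat diet library (vertical, log scale) against the normal diet library (horizontal, log scale), with 614 known lncRNAs on the left and 272 numbered ones on the right, 1 library per diet and no error bars. Solid lines mark equal levels and dashed lines 2-fold, orange marks known lncRNAs that share at least 50 bases with coding exons, and triangles mark numbered lncRNAs listed at 1 read in either library. Gm26584 and 4732463B04Rik stand below the 2-fold line at high levels, and Gm28592 stands above it. Lnc_279, which makes up most of the total to which it is scaled, lies on the line of equal levels.

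Of the nuclear and abundant lncRNAs, 3 of 23 were measured, 1 lower and 2 not called. Neat1, the scaffold of paraspeckles, was 3.01-fold lower in the high fat diet library (2.41 to 3.79), with 200 reads against 754. Malat1, a nuclear speckle lncRNA encoded next to Neat1 on chromosome 19, was 1.57-fold higher (1.35 to 1.83), with 792 reads against 630, which does not reach 2-fold. Malat1 shares near-identical stretches with 89 genes elsewhere and Neat1 with 4, and reads of those stretches could be shared. Pvt1 had 18 reads against 2, under the read minimum.

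Of the X-inactivation lncRNAs, 2 of 4 were measured. The exons of Xist overlap those of the coding gene Gm26992 on the opposite strand by 431 bases. Reads in that overlap cannot be assigned to either gene. Xist had 14 reads against 36 and was lower by the rule, with a log2 ratio of -1.04 whose interval of -2.54 to 0.29 included 0. With a pseudocount of 5 reads its ratio was -0.79, under 2-fold, which ends the call. Ftx, which shares near-identical stretches with 158 genes elsewhere, had 4 reads against 12. The hepatic metabolic list had 4 of 16 measured and none called. C730036E19Rik had 60 reads in each library (log2 ratio 0.32, interval -0.46 to 1.10), Gm10804 had 66 against 126 (-0.61), 1810008I18Rik had 8 against 16 and Platr4 2 against 4.

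Mir155hg, the host of miR-155 and the 1 measured of 12 microRNA host lncRNAs, had 8 reads against 2, under the minimum. With Gm12840, which had 46 reads against 88 (log2 ratio -0.61), it was also 1 of the 2 measured among 16 markers of non-hepatocyte cells, and neither was called. No member of the snoRNA host list (19 genes), the imprinted list (10 genes) or the 6 coding lists was listed in the table.

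The numbered lncRNAs were compared between the same libraries in their own table. Lnc_219 had 98 reads in the high fat diet library and was listed at 1 read in the normal diet library. It was 23.7-fold higher against the floor and at least 18.5-fold higher by the lower limit of its 95% interval. Against the same floor, lnc_412 was 13.05-fold, lnc_650 8.21-fold and lnc_765 5.32-fold higher. By the lower limits of their intervals they were at least 9.90-fold, 5.98-fold and 3.64-fold higher. Lnc_65 had 100 reads against 6 (log2 ratio 4.59, 95% interval 2.96 to 6.92). In the other direction, lnc_565 was listed at 1 read in the high fat diet library against 158, and was 18.2-fold lower against the floor. It was followed by lnc_79 (14.7-fold), lnc_403 (11.04-fold) and lnc_217 (5.98-fold). By the lower limits of their intervals they were at least 14.4-fold, 11.6-fold, 8.64-fold and 4.53-fold lower. Lnc_332 had 2 reads against 98, a log2 ratio of -5.08 (-10.41 to -2.53).

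The most abundant numbered lncRNA, lnc_279, held 62.3% (61.4 to 63.1) and 62.2% (61.5 to 63.0) of the read pairs of its table, a log2 ratio of 0.00 (-0.04 to 0.04). Since it makes up most of the total to which it is scaled, this ratio is drawn toward 0. Median-ratio scaling gave -0.12. The next in abundance were lnc_736 (log2 ratio -0.50), lnc_251 (0.74), lnc_748 (-0.61) and lnc_583 (0.08), none of them called. In all, 19 numbered lncRNAs were higher and 23 lower in the high fat diet library, of 117 that reached the read minimum. Of these, 4 higher and 9 lower ones were listed at 1 read in the other library, and the interval excluded 0 for 17 in each direction. Of 71 with at least 20 reads in both libraries, 44 (62.0%) differed by less than 1.5-fold. The authors' deposited table marks 18 as higher and 17 as lower, 31 of them among the 42 called here, and the other 4, named after their values were seen, are lnc_559, lnc_697, lnc_298 and lnc_723.

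The split of higher against lower lncRNAs, 28 against 30 known and 19 against 23 numbered, was not found to differ between the tables (odds ratio 1.13, two-sided Fisher's exact test, p = 0.840). This test describes the 2 libraries, since lncRNAs are not independent replicates and some may be listed in both tables. A p of this size does not show that the splits are equal.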

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

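The exact binomial test, the leaving out of lncRNAs and the scaling to known-table totals were chosen after the data were seen. Known lncRNAs, 28 higher and 30 lower, numbered 78 and 68 without a read minimum, 8 and 11 with 100 reads, 6 and 9 at 4-fold, 58 and 66 at 1.5-fold, 18 and 19 with the authors' adjusted p of 0.05 or less, 15 and 16 by the exact binomial test, and 16 and 19 without lncRNAs overlapping coding exons by any number of bases. Numbered lncRNAs, 19 higher and 23 lower, numbered 61 and 56 without a minimum, 5 and 7 with 100 reads and 12 and 14 at 4-fold. At 1.5-fold 29 were higher and 33 lower, and without those listed at 1 read 15 were higher and 14 lower. Each of these settings changes by construction which lncRNAs can be called. The other settings run include median-ratio scaling, other pseudocounts, known-table totals for the numbered table and leaving out matched lncRNAs. Under them the counts stayed within 1.5 times, but the direction with more calls did not stay the same. With a pseudocount of 5 reads, 27 known lncRNAs were higher and 22 lower, and 18 and 18 numbered ones. Median-ratio scaling moved log2 ratios by 0.01 (known) and 0.12 (numbered), and lnc_279 then had a ratio of -0.12. Alternatives of scaling and pseudocount numbered 162 over 54 named lncRNAs. Of these, 161 left the value within its counting interval, that of lnc_279 moved, and 0 reversed a call. Xist, at -0.79 with a pseudocount of 5 reads, no longer reached 2-fold, the 1 named call lost in this way. Separately, the authors' adjusted p of 0.05 or less ends the named calls of Lsmem2, A330033J07Rik, Gm44427 and Xist. Fisher's exact test of the direction split gave p = 1 at 100 reads and 0.754 at 4-fold. Summing per gene gave no value, since no name is shared by several entries. No paired analysis was possible because each diet has 1 library, and leaving a library out was impossible for the same reason. Depth limits the numbered table most, where 155 of 272 lncRNAs stayed below 20 reads, against 250 of 614 known ones.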

Other observations

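All tests in this part were chosen after the results were seen, except the test over pairs of lncRNAs overlapping the same coding gene. The lncRNAs in this and the next paragraph were also picked after their values were seen. 9530052E02Rik, opposite Irs2, the insulin receptor substrate 2 gene, had 66 reads in the high fat diet library against 210 (log2 ratio -1.35, 95% interval -1.96 to -0.77). Gm26745, opposite the proteasome gene Psmd9, had 100 against 316, and Gm26635, opposite Hic2, had 70 against 202. Toward the high fat diet library, Gm26714, opposite Tcim, had 240 against 124 (1.28), and Gm44148, opposite the interferon-induced gene Usp18, had 72 against 40 (1.17, 0.34 to 2.04). Gm15758 (102 reads against 462, with near-identical stretches in 11 genes elsewhere) and Gm26608 (124 against 478) were lower without an overlap with coding exons.

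Other lncRNAs with many reads differed by less than 2-fold, 5 of which are given as examples. Gm16548, opposite Selp and F5, the coagulation factor V gene, had 2000 reads against 2600 (log2 ratio -0.05). Gm16984, opposite the fatty acid oxidation gene Eci2, had 1770 against 2712 (-0.29), and Gm26669, opposite Zfp36l1, had 5766 against 5258 (0.46). Gm42418, which overlaps 1822 bases of an annotated ribosomal RNA gene on the opposite strand, had 566 against 976 (-0.46, -0.68 to -0.25), and Gm26917 had 3918 against 7062 (-0.53, -0.61 to -0.45).

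Known lncRNAs that overlap coding exons by at least 50 bases held most of the reads in both libraries, 216 lncRNAs with 65.7% (65.4 to 66.0) of the read pairs in the high fat diet library and 63.4% (63.1 to 63.6) in the normal diet library. Their median reads per kb of exon were 148 against 19.2 for the others (ratio 7.72). This ratio restates the pattern and does not test whether reads of the coding genes on the other strand were counted for the lncRNAs, so that explanation stays open. Near-identical copies elsewhere gave a ratio of 1.37 among lncRNAs without any overlap (23.9 against 17.4 reads per kb, permutation p = 0.191), which leaves shared reads open. Transcription of both strands at expressed coding genes would give the same excess and also stays open, since neither the strand of the reads nor coding genes were analysed here. Overlapping lncRNAs that reached the read minimum were called less often than the others, 20 of 175 against 38 of 189 (two-sided Fisher's exact test, p = 0.0310). The median reads of these 175 and 189 over both libraries were 426 against 118. A fold rule calls lncRNAs with few reads more often through counting error, but whether this accounts for the difference was not tested.

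Many numbered lncRNAs carry exactly the read numbers of a known lncRNA in both libraries. Of 72 numbered lncRNAs with at least 60 reads over both libraries, 26 matched, against a mean of 3.11 and a highest number of 7 over 80 comparisons with displaced read numbers, which argues against coincidence for most of them. With at least 200 reads, 8 of 29 matched, and the highest displaced number was 1. The same transcripts may therefore be listed in both tables, as for lnc_337 with Gm26608, lnc_589 with 4933440J02Rik and lnc_176 with Gm29483, the 3 matched ones that were called. Lnc_279, with 15738 and 22804 reads, comes close to Gm26809, with 15728 and 22798, and matched lncRNAs have log2 ratios higher by 0.21 in the numbered table through the table totals alone.

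Gm9968 and Gm15713, which both overlap the span of Zbtb20, had log2 ratios that differed by 0.0429 (95% interval -0.24 to 0.32). The pair was noticed for its likeness, so its own values cannot test whether 1 source of reads at the locus could account for both, and this stays open. A further test took 8 pairs of lncRNAs that overlap the span of the same coding gene, this pair included and Gm26573 in 2 of them. The mean absolute difference was 0.589 against 0.836 for random pairs of like read numbers (one-sided permutation test with 10000 draws, p = 0.190), and 0.667 without the Zbtb20 pair. The prediction written before that result took a p of 0.05 or more as evidence against a joint difference, but 8 pairs are too few for that reading, and a p that misses the threshold does not exclude it. The share of diet in these ratios was not tested, with 1 library per diet.

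Numbered lncRNAs that reached the read minimum were called more often than known ones, 42 called against 75 not, compared with 58 against 306 (odds ratio 0.338 for known against numbered, two-sided Fisher's exact test, p = 1.1e-05). The numbered table has fewer reads per lncRNA, and lncRNAs are not replicates, so this describes the 2 tables. Matched lncRNAs may also sit on both sides of this comparison. Of the numbered calls, 4 higher and 9 lower ones were listed at 1 read in the other library, against 0 and 0 known ones.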
